A study of Danio rerio with 15 samples.

How the data were processed

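Messenger RNA was sequenced from whole zebrafish embryos of the Tropical 5D strain, a wild-type laboratory line. Embryos were exposed from 8 hours post fertilization to 1 of 4 short-chain per- and polyfluoroalkyl substances (PFAS) at 47 uM, or to 0 uM as the control, all in 0.5% methanol, and sampled at 48 hours post fertilization. The compounds were perfluorobutane sulfonamide (FBSA), perfluorobutane sulfonic acid (PFBS), perfluoropentanoic acid (PFPeA) and a fluorotelomer sulfonic acid (42FTS). Each of the 15 libraries held RNA of 10 pooled embryos, with 3 libraries in each of the 5 groups. Per the labels' protocols, libraries were made from RNA selected with oligo(dT) beads and read on a BGISEQ-500 instrument. The toxicity and body burden assays that the series' design also names were not analysed here.

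Reads were assigned to genes by the authors, and their table held whole-number read counts per gene that were not normalized. The submitters' processing notes list HISAT2, HTSeq, Bowtie2, RSEM and DESeq2 and the genome build GRCz11, without versions or roles, and the deposited count table ends in the category lines that HTSeq writes. Whether counting used the strand of the read is not given in the sources used here, so overlapping and antisense genes could share reads. The header of the count table gave 1 name to a pair of PFBS columns, which are called PFBS a and PFBS b here and carry no replicate number. The other PFBS library is called PFBS 2.

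The authors' deposited table of differential expression gave a log2 fold change, a p-value and a q-value (called Q here) per gene for each compound against the control, per the file headers, and listed only genes with an FBSA Q under 0.05. It also held 45 columns of values per sample and 15 columns of averages, 60 in all, which were not used. The authors' deposited enrichment table gave numbers of genes, p-values and q-values for Gene Ontology (GO) terms among the genes changed by FBSA. Their deposited transcription factor table gave the ratio of observed to expected network objects and a p-value per factor. Per the file headers, zebrafish genes had been converted to human gene identifiers for that table. How these enrichments were computed is otherwise not given in the sources used here, and their values are printed as the authors' own.

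The count table held 47048 gene entries named by symbol. Of these, 16469 carried a numbered suffix (such as insig1_1) beside an entry with the same stem, and together they took 5.12% of the counts. Reads could be split between such copies, so a suffixed entry is reported as uncertain. The category lines that name no gene stayed out of library sizes and tests. Of all counted reads, 63.7% to 66.6% per library fell in genes, 11.5% to 12.5% in no feature, 14.3% to 15.7% aligned to more than 1 place, 6.32% to 9.94% did not align and 0.131% to 0.139% were ambiguous. Gene counts ranged from 24249287 to 32686343 per library. At that depth and with 3 libraries per group, the median 95% confidence interval of a log2 fold change reached 0.44 to either side, and 79.1% of genes tested for FBSA against the control had an interval of under 1 to either side.

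Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by edgeR's filterByExpr with its default settings, which left 23874 entries, 3391 of them suffixed. Libraries were scaled by trimmed mean of M-values (TMM). A quasi-likelihood model with robust dispersion was fitted to all 15 libraries with group as the only term, so that the groups shared 1 estimate of the spread. Each of the 10 pairs of groups was compared by the two-sided quasi-likelihood F-test, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05 on the adjusted p. Fold changes are given as log2 with their standard error (SE) or 95% confidence interval (CI), and levels as TMM-scaled CPM (edgeR's library-scaled counts) with the standard deviation (SD).

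Fixed lists of genes for 39 pathways and cell types were written before the data were examined. Of 1258 listed symbols, 1178 matched an entry by symbol and 36 by a synonym, 44 did not match, and 1121 were tested. Lists were tested against all other genes with camera of limma 3.58.1 on voom log2 CPM, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the 39 lists. The test was repeated with a correlation estimated from the residuals, and with fry, which asks whether the genes of a list move on balance in 1 direction. The number of members past the gene test is given over all genes tested and adjusted over the list alone. Adjusted p-values of single genes below come from edgeR and those of lists from camera.

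The rule for naming genes was also fixed before the data were examined. For a comparison with the control it took the 12 largest increases and the 12 largest decreases among genes past the test that had a symbol that was not a clone name, a mean of at least 1 CPM, and all 3 exposed libraries on the same side of all 3 control libraries. Where no gene passed, the 3 with the lowest p were named as not passing. Between compounds the rule took the 5 largest increases and 5 largest decreases, and in each list up to 4 members past the test, otherwise up to 2 that were not.

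The edgeR and DESeq2 code was tested on counts simulated from the mean levels, spread and sizes of all 15 libraries. In the simulated FBSA libraries 50 genes were changed at each fold among 23561 genes. These were drawn from genes with a mean of at least 1 CPM. They were far fewer than the genes called for FBSA in the data, so recovery in the data may differ. For FBSA against the control, edgeR recovered 20% of genes changed 1.5-fold, 52% of those changed 2-fold and 88% of those changed 4-fold, and 6% at a smaller fold. DESeq2 recovered 24%, 62% and 92% of the first 3 and 10% of the last. Of 84 edgeR calls, 1 was false.

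Replicates of a group were compared by a chi-square test of their counts, and no pair agreed within sampling noise (chi-square over degrees of freedom 10.7 to 21.3), so each library counted as 1 sample. Alternatives fixed before the data were examined were the RLE normalization, no filter on low counts, DESeq2 1.42.0, a fit of only the 2 groups compared, the replicate number as a block, a minimum change of 2-fold, and leaving out each library in turn. Added after the data were seen were summing numbered copies into their stem, leaving out the 2 libraries with more unaligned reads, leaving out PFBS to set beside the block, the same omissions for the gene lists, a simulation of the control libraries, and simulations with 1 control left out. Gene coordinates are not given, because no annotation of GRCz11 was used here.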

Results

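Transcript levels were measured in 15 pools of whole zebrafish embryos, 3 pools for each of 4 fluorinated compounds at 47 uM and 3 for the control without compound. All 4 compounds end in a perfluorobutyl chain and differ in the rest of the molecule. FBSA carries a sulfonamide and PFBS a sulfonic acid on the same chain. PFPeA carries a carboxylic acid, and in 42FTS an ethyl spacer lies between the chain and a sulfonic acid. The question put to the data was whether head groups on a short fluorinated chain differ in their effect on the transcriptome of the embryo. Reads counted in genes ranged from 32420346 to 32686343 per library in FBSA, 32195020 to 32367808 in PFBS, 31853175 to 32215061 in PFPeA, 24249287 to 32494323 in 42FTS and 24552649 to 32630731 in the control. The lowest totals were those of Control 3 and 42FTS 2, in which 9.92% and 9.94% of reads did not align, against 6.32% to 6.73% in the other 13 libraries. On the first principal component, which held 14.8% of the variance, FBSA 2 scored 75.2, FBSA 1 and FBSA 3 scored 36.5 and 34.5, and the other 12 libraries lay between -19.6 and 9.05. Nothing in the labels says that the pools of a group came from separate clutches, so p-values measure the spread between these pools.

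FBSA changed the levels of 2274 of 23874 genes tested against the control, 1260 of them higher and 1014 lower. Both zebrafish copies of slc16a9, which belongs to the monocarboxylate transporter family, were among the largest increases: slc16a9b rose from 24.2 ± 3.07 to 118 ± 18.8 CPM (SD, n = 3 per group) and slc16a9a rose by 3.43 on the log2 scale (SE 0.46). The pituitary hormone gene prl (prolactin) rose from 3.15 ± 0.425 to 14.7 ± 1.31 CPM, and the natriuretic peptide genes nppb and nppa, which the heart expresses, rose by 2.32 (SE 0.41) and 1.38 (SE 0.14). The immune gene irg1l rose by 3.36 (SE 0.48), from 5.51 ± 1.31 to 56.7 ± 27.3 CPM. Among decreases, igfn1.3, a gene of the immunoglobulin and fibronectin domain family, fell from 29.1 ± 3.91 to 2.69 ± 1.94 CPM, and the muscle AMP deaminase gene ampd1 from 347 ± 7.31 to 104 ± 46.2 CPM. Adjusted p-values were 0.000433 for slc16a9a, 1.14e-06 for slc16a9b, 7.32e-06 for prl, 0.00328 for nppb, 3.4e-05 for nppa, 0.00204 for irg1l, 0.00138 for igfn1.3 and 0.00418 for ampd1.

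Other large increases were those of mcoln3a (log2 2.64), lrrc58a (95% CI 1.55 to 3.26), agxtb (2.27), irf3 (2.17), slc2a12_1 (2.15), epm2a (2.15) and maff (2.01). The solute carrier slc2a12 is a glucose transporter, epm2a encodes a glycogen phosphatase and mcoln3a a cation channel of endosomes. Other large decreases were those of insig1_1 (-2.91), nat9_1 (-2.62), tomm22 (-2.62), znf839_1 (-2.52), magoh (-2.48), clic5a (-2.45), mfsd13a_1 (-1.99), the myosin heavy chain gene myhb (-1.96), the glycogen debranching enzyme gene aglb (-1.89) and lgals3bpb (-1.64). The entries with a numbered suffix are copies whose reads could be shared with another entry, so their values are uncertain. Control levels of several of the decreased genes scattered widely: those of insig1_1 were 4.13, 7.16 and 11.7 CPM, those of tomm22 6.61, 21.1 and 17.6 CPM, and those of magoh 4.99, 33.8 and 8.75 CPM, in Control 1, 2 and 3. Of the 24 genes named so far besides nppa, 8 lost the call when 1 library was left out: agxtb (without Control 2, 2.06, or FBSA 2, 1.58), nat9_1 (Control 2, -1.16, FBSA 1, -2.46, or FBSA 2, -2.77), magoh (FBSA 1, -2.49, FBSA 2, -2.51, or FBSA 3, -2.43), irf3 (any control, 2.11 to 2.21, or FBSA 2, 1.75), maff (any library but FBSA 3, 1.68 to 2.03), tomm22 (any but Control 1, -2.75 to -2.30), mfsd13a_1 (any but Control 1, -2.11 to -1.61) and clic5a (any, -2.68 to -2.20). The log2 change of magoh was -1.26 without Control 2, and tomm22 (-2.64) and magoh (-2.26) also lost the call with the library number as a block. In a fit of only the 2 groups 7 lost the call, agxtb (2.27), maff (2.01), igfn1.3 (-3.43), nat9_1 (-2.62), magoh (-2.48), myhb (-1.95) and ampd1 (-1.73), and without the low-count filter maff (2.00) and clic5a (-2.46) did.

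Most changes were small. Of the called genes, 86.7% changed by under 2-fold, with a median of 1.45-fold for those higher and 1.32-fold for those lower, and 302 changed at least 2-fold, 235 up and 67 down. For 6696 genes (28.0% of those tested, where chance gives 10%) all 3 FBSA libraries lay on the same side of all 3 controls, and 2253 of these were among the called genes. The count fell by over 1.5 times to 1020 without FBSA 2, to 1296, 1309 and 1430 without Control 1, 2 and 3, to 1228 without Control 3 and 42FTS 2 together, and to 855 in a fit of only the 2 groups.

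**Figure D1:**
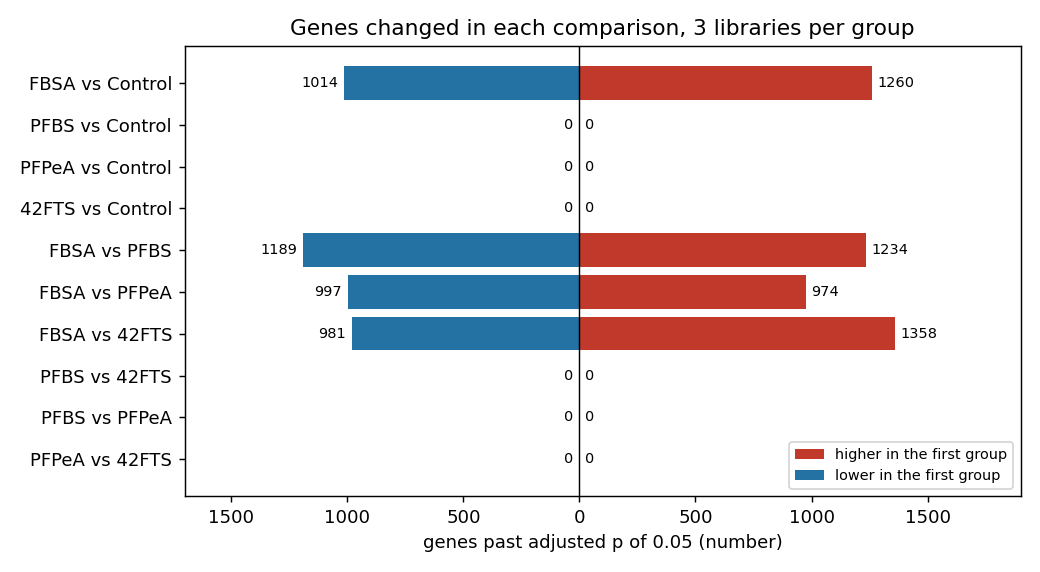
Numbers of genes past edgeR's test in each of the 10 comparisons, with higher and lower genes drawn separately. The 4 comparisons that include FBSA gave 1971 to 2423 genes, and the 6 that do not gave 0.

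Genes of the heart, of ion transport, of the hatching gland and of vessels were higher in FBSA. In the heart list, 6 of 20 tested members rose and 1 fell over all genes tested, and 9 rose and 1 fell adjusted over the list alone (median log2 0.26, adjusted p = 0.0002). With nppa and nppb, the contractile protein genes actc1a (0.41) and myl7 (0.29) rose. Of 26 genes of ionocytes, the ion-transporting cells of the skin, 7 rose and 2 fell, and 8 and 2 adjusted over the list alone (median 0.28, adjusted p = 0.0015). The sodium pump subunits atp1b1b (0.97, SE 0.06) and atp1a1a.2 (0.88, SE 0.07) and the carbonic anhydrase ca2 (0.79) rose, and the ammonium transporter rhbg fell by 0.48 on the log2 scale. Of 7 hatching gland genes 5 rose, on both adjustments (median 0.86, adjusted p = 2.4e-05), among them the hatching enzymes he1a (0.86) and he1b (1.09). Of 30 genes of blood vessel endothelium 6 rose, and 8 adjusted over the list alone (median 0.21, adjusted p = 0.00014), with the transcription factor sox7 at 0.37. Single libraries moved some of these counts: 3 hatching gland genes passed higher without FBSA 2, and of the vessel genes 1 passed without FBSA 2 and 2 without Control 1 or Control 2. The 1 lower heart gene did not pass by edgeR without Control 1, Control 2, FBSA 1 or FBSA 2, and 1 ionocyte gene passed lower without Control 1, Control 2, Control 3 or FBSA 2. The call of myl7 (0.29) was lost in a fit of only the 2 groups. Outside FBSA, PFPeA 1 (0.386) and 42FTS 1 (0.359) scored highest on the hatching gland list, where FBSA scored 0.498 to 0.932, and 42FTS 2 (0.211) on the ionocyte list. With the preset correlation 18 of the 39 lists were called for FBSA. These 4 lists were the only ones still called with an estimated correlation, at adjusted p = 0.025 for heart and vessels and 0.029 for ionocytes and the hatching gland.

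Neuronal genes were lower, and genes of neural progenitors and of the cell cycle were higher. Of 39 neuronal genes 16 fell and 0 rose, and 21 fell and 2 rose adjusted over the list alone (median -0.27, adjusted p = 5.5e-09, and 0.25 with an estimated correlation). Examples were the RNA-binding protein gene elavl4 (-0.63), the tubulin gene tubb5 (-0.45) and the synaptic genes snap25a (-0.34) and stxbp1a (-0.27). Of 26 genes of glia and neural progenitors 8 rose and 1 fell, and 10 and 1 adjusted over the list alone (median 0.45, adjusted p = 0.00011, and 0.077 with an estimated correlation), including the Notch ligands dla (0.71) and dld (0.63) and the glial enzyme gene glula (0.55). In the cell cycle list 18 of 35 rose, and 24 adjusted over the list alone, with none lower (median 0.28, adjusted p = 2.3e-12, and 0.092 with an estimated correlation), including the cyclins ccna2 (0.35) and ccne2 (0.41). FBSA 2 stood apart from the other 2 FBSA libraries in all 3 lists. Its list score, the mean log2 CPM minus the control mean, was -0.461 for neurons, against -0.103 and -0.139 in FBSA 1 and FBSA 3, 0.486 for progenitors against 0.219 and 0.172, and 0.403 for the cell cycle against 0.165 and 0.192. Control 3 scored -0.117 for neurons, lower than FBSA 1. Neuronal genes past the test were 10 without Control 1 and 9 without FBSA 2 (median -0.18), and cell cycle genes 11 without Control 1, 10 without Control 2 and 10 without FBSA 2. The progenitor median was 0.29 without Control 1, 0.26 without Control 3 and 0.16 without FBSA 2, with at least 8 genes higher in each. The 1 lower progenitor gene did not pass by edgeR without Control 1, Control 2, Control 3 or FBSA 2.

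**Figure D2:**
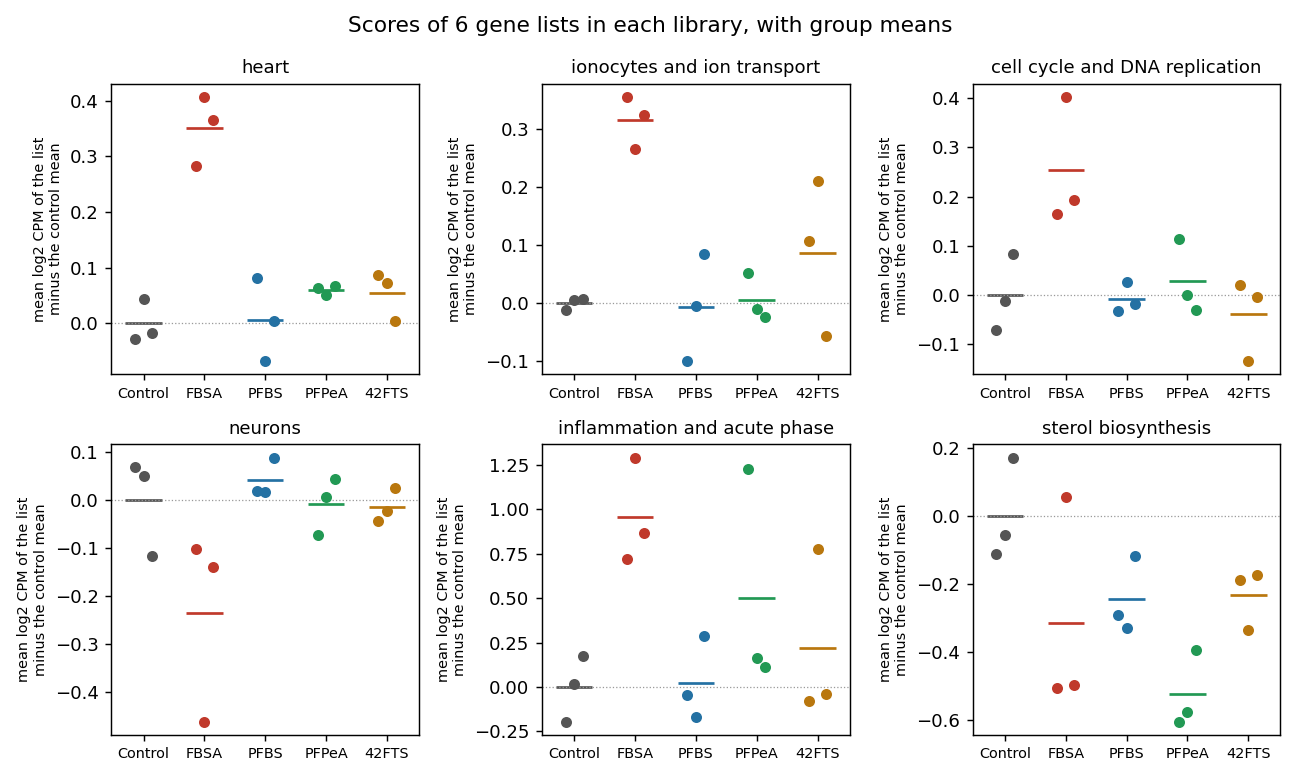
Score of 6 gene lists in each of the 15 libraries, as the mean log2 CPM of the list's tested members minus the mean of the control libraries. In the heart and ionocyte lists the 3 FBSA libraries lie together above the control, at 0.283 to 0.407 and 0.266 to 0.356, while in the neuron list FBSA 2 lies at -0.461.

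Immune genes were higher in FBSA, and stress genes in part. Of 28 genes of inflammation and the acute phase 10 rose, and 16 adjusted over the list alone (median 0.74, adjusted p = 1.2e-07, and 0.25 with an estimated correlation). Besides irg1l, the prostaglandin synthase gene ptgs2a (0.81) and the complement gene c3a.1 (0.84) rose. The score of this list was 0.719, 1.29 and 0.866 in FBSA 1, 2 and 3, but also 1.23 in PFPeA 1 and 0.777 in 42FTS 2, and at most 0.286 in the other 10 libraries. Of the inflammation genes 5 passed without Control 1, 4 without Control 2, 6 without Control 3 and 3 without FBSA 2. Of 24 genes of macrophages and neutrophils 4 rose, and 5 adjusted over the list alone (median 0.42, adjusted p = 0.0092, 0.22 with an estimated correlation, 0.0508 without FBSA 2, with 1 gene past the test), among them cebpa (0.41). FBSA scored 0.273 to 0.705 on this list, 42FTS 2 scored 0.366 and 42FTS 1 scored 0.228. In the p53 list 4 of 19 rose, and 5 adjusted over the list alone (median 0.39, adjusted p = 0.00065, and 0.35 with an estimated correlation), including eif4ebp3l (0.83) and tp53inp1 (0.54). That list scored 0.226 to 0.423 in FBSA, and also 0.558 in PFPeA 1 and 0.323 in 42FTS 2, and 2 genes passed without Control 1 or Control 2. Of 26 genes of the NRF2 oxidative stress response 4 rose, and 5 adjusted over the list alone (median 0.19, adjusted p = 0.023). The adjusted p was 0.25 with an estimated correlation, 0.134 without Control 1 and 0.0845 without FBSA 3. Among those that rose were nfe2l2a (0.51) and nfe2l2b (0.95), which encode zebrafish forms of NRF2 and are regulators, not targets. Control 3 (0.208) scored above all 3 FBSA libraries (0.134 to 0.188) on this list, and without Control 1 the median was 0.09 with 2 genes past the test. Endoplasmic reticulum stress and integrated stress response genes moved both ways: of 37, 12 rose and 8 fell, and 15 and 10 adjusted over the list alone, and the list was not called (adjusted p = 0.075, and 0.0493 without FBSA 1), with 4 lower without Control 1 or FBSA 2 and 5 without FBSA 3. Here slc3a2b (0.60), atf4a (0.43) and sesn2 (1.34), of the amino acid response, rose, and the chaperone gene hyou1 fell by 0.40 on the log2 scale. Of 26 heat shock and folding genes 2 rose and 2 fell, and 3 and 4 adjusted over the list alone (adjusted p = 0.70), with serpinh1b at 0.76 and dnaja1 at -0.51. In a fit of only the 2 groups the calls of ptgs2a (0.81), nfe2l2b (0.95) and serpinh1b (0.76) were lost.

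Genes of lipid synthesis were lower. Of 19 genes of fatty acid synthesis and triglyceride storage 4 fell, on both adjustments (median -0.40, adjusted p = 0.016, and 0.080 with an estimated correlation), including the elongase elovl2 (-1.54, SE 0.25) and the desaturase fads2 (-1.29, SE 0.21), which make polyunsaturated fatty acids. The call was lost without Control 2 (adjusted p = 0.0572, median -0.19) or FBSA 3 (0.0681, median -0.18), and without Control 3 the median was -0.23. Of 25 genes of sterol biosynthesis 5 fell, on both adjustments (median -0.17, adjusted p = 0.0054, 0.52 with an estimated correlation, 0.102 without FBSA 1 and 0.130 without FBSA 3), with sqlea, of the cholesterol pathway, at -0.92. Without FBSA 2 the sterol median was -0.29, and 3 genes passed without Control 1, Control 3 or FBSA 1 and 2 without Control 2 or FBSA 3. The sterol score of FBSA 2 was 0.0559, against -0.507 and -0.497 in FBSA 1 and FBSA 3. Among 39 genes of fatty acid oxidation and PPAR targets 5 rose and 1 fell, on both adjustments, and the list was not called (median 0.00, adjusted p = 0.99). Of these, 3 passed higher without Control 2, Control 3 or FBSA 2, and the 1 lower gene did not pass by edgeR without Control 1, Control 2, Control 3, FBSA 2 or FBSA 3. The mitochondrial carriers ucp3 (1.68, SE 0.26) and ucp2 (0.64) were among those that rose. Of 22 lipoprotein and yolk export genes 2 rose and 3 fell, on both adjustments (adjusted p = 0.78), with the protease gene ctsl.1 at 1.54 and the apolipoprotein gene apoa4a at -0.89. In that list 1 passed higher without Control 1, Control 3 or FBSA 2 and 1 lower without Control 1, Control 2 or FBSA 2. Of 58 genes of oxidative phosphorylation 3 fell, on both adjustments (median -0.12, adjusted p = 5.4e-05, and 0.40 with an estimated correlation), cox6b1 at -0.89, and 14 of 65 ribosomal protein genes rose, 24 adjusted over the list alone (median 0.14, adjusted p = 2.3e-12, and 0.34 with an estimated correlation), rplp1 at 0.28. The call of cox6b1 was lost without Control 1 or Control 2, at -0.84 in both, and those of cox6b1 (-0.89) and rplp1 (0.29) in a fit of only the 2 groups. For oxidative phosphorylation 1 gene passed without Control 3 or FBSA 2 and 6 without FBSA 1. For ribosomal proteins 5, 8 and 2 passed without Control 1, 2 and 3, and 5, 3 and 9 without FBSA 1, 2 and 3. FBSA 3 scored 0.0702 on the ribosomal list, under PFPeA 2 (0.125), PFPeA 3 (0.0896) and PFBS 2 (0.0875), and -0.0963 on oxidative phosphorylation, between Control 1 (-0.0909) and PFPeA 1 (-0.106).

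Lists of the skin, gut and kidney and of glucocorticoid response were also higher. Of 36 genes of the epidermis 12 rose and 3 fell, and 15 and 3 adjusted over the list alone (median 0.24, adjusted p = 0.00013, and 0.074 with an estimated correlation), with anxa1b at 1.46 (SE 0.11) and the tight junction gene cldne at 0.98. In the intestine and kidney list 5 of 25 rose and 1 fell, and 10 and 3 adjusted over the list alone (median 0.28, adjusted p = 0.024, 0.085 with an estimated correlation, 0.0571 without Control 2), with 2 higher without Control 1 or Control 2 and 3 without FBSA 1 or FBSA 2, the phosphate transporter slc20a1b at 0.82. The glucocorticoid and circadian list had 3 of 34 higher and 1 lower, and 5 and 1 adjusted over the list alone (median 0.27, adjusted p = 0.026, 0.35 with an estimated correlation, 0.0603 without Control 2 and 0.104 without FBSA 3). In it the kinase gene sgk1 was at 0.63 and the steroid enzyme gene cyp17a1 at -0.70, and 1 passed higher without Control 3 and 2 lower without FBSA 3. Of the epidermal genes 7 passed higher and 1 lower without FBSA 2, and their median was 0.16 without Control 2 and 0.15 without FBSA 3.

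The remaining lists were not called. In skeletal muscle 7 of 62 rose and 8 fell, and 7 and 9 adjusted over the list alone (adjusted p = 0.23), with the actin genes acta1a (-0.58) and acta1b (-0.80) lower and desma (0.81) higher. Of the muscle genes 4 passed higher without Control 1 or Control 3, and 5 passed lower without Control 1 or FBSA 2. In liver 5 of 37 rose, and 8 rose and 1 fell adjusted over the list alone (adjusted p = 0.094, and 0.0122 without FBSA 2), c9 at 0.69, with 2 higher without Control 2 and 3 without Control 3 or FBSA 1. In the pancreas 3 of 17 rose, and 6 adjusted over the list alone (adjusted p = 0.12), the somatostatin gene sst2 at 1.73, with 1 higher without Control 1 or FBSA 2. In the hypoxia and glycolysis list 5 of 37 rose and 4 fell, and 6 and 5 adjusted over the list alone (adjusted p = 0.46), igfbp1a at 1.06 and ldha at -0.87, with 3 higher and 2 lower without Control 2, Control 3 or FBSA 2. Of 14 carbonic anhydrases 2 rose and 1 fell, and 4 and 2 adjusted over the list alone (adjusted p = 0.23), ca9 at 0.99, with a median of 0.16 and a mean of -0.02. That median was 0.29 without Control 3, 0.01 without FBSA 2 and 0.24 without FBSA 3, and the 1 lower gene did not pass by edgeR without Control 2, FBSA 1 or FBSA 2. Of 12 aryl hydrocarbon receptor targets 2 rose, gstp1 and sult6b1, both at 0.28, and 3 adjusted over the list alone (adjusted p = 0.23). Both lost the call without Control 1, Control 2 or FBSA 2 (0.22 to 0.30), and sult6b1 also without FBSA 3 (0.27). In this list 1 other member passed higher without FBSA 2, and 1 passed lower without FBSA 3. By edgeR 0 of 32 genes of PXR and CAR type xenobiotic metabolism passed on either adjustment (adjusted p = 0.20), with 8 at an unadjusted p under 0.05 and 4 higher by DESeq2, among them cyp2v1 (0.32) and cyp2ad3 (0.37). Over all genes, 3 passed higher without FBSA 1, 2 higher without Control 3 and 1 lower without FBSA 3. The following lists had the same members past the test on both adjustments. Erythrocytes had 1 of 28 higher (adjusted p = 0.23) and organic anion and bile salt handling 1 of 25 lower (0.99). Retina had 2 of 25 higher and 1 lower (0.70), lens crystallins 2 of 40 higher and 1 lower (0.37, and 0.0161 without FBSA 2), and pigment cells 2 of 26 lower (0.90). Notochord and cartilage had 1 of 27 higher and 1 lower (0.90), fibrous collagen 1 of 43 higher and 2 lower (0.34), and the thyroid axis 1 of 17 higher and 1 lower (0.90), dio3b at 0.97 and duox at -0.93. Of 8 estrogen response genes 0 passed by edgeR (0.73), 1 at an unadjusted p under 0.05 and 0 by DESeq2, vtg1 with a 95% CI of 0.67 to 4.32 (adjusted p = 0.082). For retinoic acid signaling 1 of 24 rose and 2 fell, and 1 and 3 adjusted over the list alone (0.66), hoxb6b at -2.42 (call lost without Control 1, -2.34, Control 3, -1.79, FBSA 2, -2.33, or FBSA 3, -2.28). In a fit of only the 2 groups the calls of sult6b1 (0.28), duox (-0.93) and hoxb6b (-2.42) were lost. Counts by edgeR in these lists moved when 1 library was left out. Without Control 1, retina had 1 higher and 0 lower, lens 0 higher, pigment cells 1 lower, collagen 1 lower and retinoic acid 0 on either side. Without Control 2, erythrocytes had 0 higher and 1 lower, organic anion handling, pigment cells and notochord 0 on either side, retina 2 lower and retinoic acid 1 lower alone. Without Control 3, organic anion handling and retinoic acid had 0 on either side, lens and notochord 0 higher, and pigment cells and collagen 1 lower. Without FBSA 1, lens had 0 higher and 2 lower and the thyroid axis 2 lower. Without FBSA 2, erythrocytes, pigment cells, notochord and retinoic acid had 0 on either side, organic anion handling 1 higher alone, retina 1 higher alone, lens 0 lower and collagen 0 higher. Without FBSA 3, lens had 0 lower, pigment cells 1 lower, notochord 2 lower, collagen 4 lower and the thyroid axis 2 higher. Median, mean and test differed in sign in organic anion handling, lens, pigment, notochord, thyroid and retinoic acid lists, as in the carbonic anhydrases.

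The authors' deposited table listed 1909 genes for FBSA against the control, 1126 higher and 783 lower. Of the 1741 found among the genes tested here, 1309 were also called by edgeR, 1307 of them in the same direction. Across the genes, the log2 fold changes of the authors' deposited table and those fitted here correlated with r = 0.954. Genes are not independent replicates, and both sets of values come from the same libraries. The authors' deposited table also listed only genes with an FBSA Q under 0.05, so this overlap is no independent support. By the authors' deposited table, slc16a9b was 2.30 higher (Q = 2.17e-72), nppb 2.28 higher (Q = 1.05e-11) and igfn1.3 lower at -3.29 (Q = 5.36e-05). For clic5a the authors' deposited table gave -0.58 (Q = 0.0116), a smaller decrease than the -2.45 fitted here. Among 2447 GO terms of the authors' deposited table, 52 had a Q under 0.05. Proteolysis in protein catabolism led these authors' deposited table values with 24 of 66 genes (Q = 4.36e-07). In the authors' deposited table, unsaturated fatty acid biosynthesis followed with 9 of 13 genes (Q = 0.000113), the transmembrane electrochemical gradient with 9 of 15 (Q = 0.000451) and the mitotic cell cycle with 25 of 105 (Q = 0.000635). Sodium export and potassium homeostasis had 8 of 14 genes each (Q = 0.00165), potassium import 17 of 61 (Q = 0.00199) and the 3 terms of fatty acid elongation 7 of 12 each (Q = 0.00305) in the authors' deposited table. The authors' deposited table of transcription factors gave SP1 249 interacting objects against 141.4 expected (ratio 1.76), C/EBPbeta a ratio of 2.02, HIF1A 1.88, ESR1 1.55 and the glucocorticoid receptor (GCR) 1.23.

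PFBS, the sulfonic acid of the same chain, changed 0 of 23874 genes against the control by edgeR, with 925 genes at an unadjusted p under 0.05, where chance gives 1194, and 6 genes by DESeq2. Of the 24 genes named for FBSA 0 passed by edgeR and 1, insig1_1, by DESeq2, but the 95% CI excluded 0 for 5: insig1_1 (-2.58), magoh (-2.51), tomm22 (-2.28), nat9_1 (-2.09) and znf839_1 (-2.06). Among the other 19, slc16a9b was at -0.17 (95% CI -0.46 to 0.12), prl at 0.37 (-0.02 to 0.76), nppb at 0.26 (-0.62 to 1.14) and igfn1.3 at 0.32 (-0.54 to 1.18). The 3 genes with the lowest p, which did not pass by edgeR, were insig1_1 (-2.58, adjusted p = 0.864), dnajc5gb (-1.27, 0.999) and the glutaminase gene gls2b (-1.95, 0.999), and DESeq2 called the first 2 lower. Lists called with the preset correlation were lower for sterol biosynthesis (0.00035), heat shock (0.005) and fatty acid synthesis (0.023) and higher for skeletal muscle (0.00014), ribosomal proteins (1.3e-05), oxidative phosphorylation (0.0023) and neurons (0.023), each as an adjusted p with medians of -0.18 to 0.08. None was called with an estimated correlation, where the adjusted p was 0.42 for fatty acid synthesis, 0.93 for neurons and 0.87 for the other 5. In these lists 0 members passed over all genes tested, and insig1_1 alone adjusted over the list alone. The adjusted p rose over the threshold for the sterol list without Control 3 (0.0977), heat shock without Control 3 (0.429) or PFBS b (0.518), fatty acid synthesis without Control 2 (0.401), Control 3 (0.0977) or PFBS 2 (0.195), ribosomal proteins (0.668) and oxidative phosphorylation (0.341) without PFBS 2, and neurons without any of Control 2, Control 3, PFBS 2, PFBS a or PFBS b (0.0515 to 0.221).

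PFPeA, the carboxylic acid, also changed 0 genes by edgeR, with 1243 at an unadjusted p under 0.05 and 15 by DESeq2. Sterol biosynthesis was lower as a list. Its 25 tested members had a median log2 of -0.54 (adjusted p = 5.1e-21, and 0.13 with an estimated correlation), and 16 fell adjusted over the list alone, although 0 passed over all genes tested. The sterol regulator gene srebf2 was at -0.32 and mvda, of the mevalonate pathway, at -0.72, neither past the test over all genes. The list score was -0.606, -0.576 and -0.394 in the 3 PFPeA libraries and -0.113, -0.0581 and 0.171 in the controls. Fatty acid synthesis was also lower (median -0.12, adjusted p = 0.00015, and 0.033 with an estimated correlation), with 2 of 19 members lower adjusted over the list alone, fads2 (-0.92) and elovl5 (-0.58). The list of inflammation was higher (median 0.40, adjusted p = 3.1e-05, 0.79 with an estimated correlation), with 0 of 28 members past either adjustment, il1b at 3.35 (SE 1.01), and was not called without PFPeA 1 (0.281). Ribosomal proteins (adjusted p = 5.5e-06, and 0.523 without PFPeA 2), skeletal muscle (0.019, and 0.0736, 0.0705 and 0.749 without Control 2, PFPeA 2 and PFPeA 3) and oxidative phosphorylation (0.036, and 0.0736, 0.118, 0.266 and 0.884 without Control 2, Control 3, PFPeA 2 and PFPeA 3) were higher by medians of 0.04 to 0.05, each with an adjusted p of 0.79 with an estimated correlation and with 0 members past either adjustment. The genes with the lowest p, not passing, were tmx2a (3.52, adjusted p = 0.154), mrps16_1 (2.80, 0.314) and scarb2a (-0.59, 0.314) by edgeR, and DESeq2 called all 3. By edgeR mrps16_1 passed without PFPeA 3 (3.25) and tmx2a without the low-count filter (3.51). Of the 24 genes named for FBSA 0 passed by edgeR or DESeq2, but the 95% CI excluded 0 for 6: magoh (-2.19), insig1_1 (-1.70), maff (1.49), znf839_1 (-1.41), nat9_1 (-1.36) and irf3 (1.17). For scarb2a the authors' deposited table gave -0.61 for PFPeA (Q = 1.98e-05) and for mvda -0.76 (Q = 0.00595). The other 4 of 6 genes of the authors' deposited table with a PFPeA Q under 0.05 were znf703 (0.27), h1f0 (0.39), c9 (0.33) and cp (0.29).

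The telomer acid 42FTS changed 0 genes by edgeR, with 972 at an unadjusted p under 0.05 and 14 by DESeq2. The lowest p belonged to rbfox1l_1 (-0.87, adjusted p = 0.523), insig1_1 (-2.51, 0.574) and the carboxylesterase gene ces2 (-0.50, 0.597), and 0 of these passed by edgeR while DESeq2 called all 3 lower. By edgeR ces2 passed without Control 3 (-0.62). The suffixed entries rbfox1l_1 and insig1_1 are uncertain, and rbfox1l_1 deviated from its group means against its stem rbfox1l (r = -0.716). Of the 24 genes named for FBSA 0 passed by edgeR and 1, insig1_1, by DESeq2, but the 95% CI excluded 0 for 7: insig1_1, tomm22 (-2.37), nat9_1 (-2.17), magoh (-2.09), znf839_1 (-1.32), slc2a12_1 (0.93) and prl (0.49). Among the other 17, slc16a9b was at 0.07 (95% CI -0.22 to 0.36), nppb at -0.10 (SE 0.42) and igfn1.3 at 0.14 (SE 0.39). Sterol biosynthesis (median -0.20, adjusted p = 0.001) and lens crystallins (median -0.13, adjusted p = 0.00016) were lower as lists, both at adjusted p = 0.90 with an estimated correlation, with 1 sterol gene (insig1_1) and 0 lens genes lower adjusted over the list alone and 0 over all genes. Leaving out 42FTS 2 gave 0.0818 for both, and leaving out Control 3 gave 0.127 for the sterol list. By the authors' deposited table, cand2 (-1.52, Q = 6.54e-18) was the 1 gene of the 1909 with a 42FTS Q under 0.05, and MGC174155 (-0.46, Q = 1.78e-05) the 1 with a PFBS Q under 0.05. That table listed genes by their FBSA Q, so other genes of these compounds do not appear in it.

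**Figure D3:**
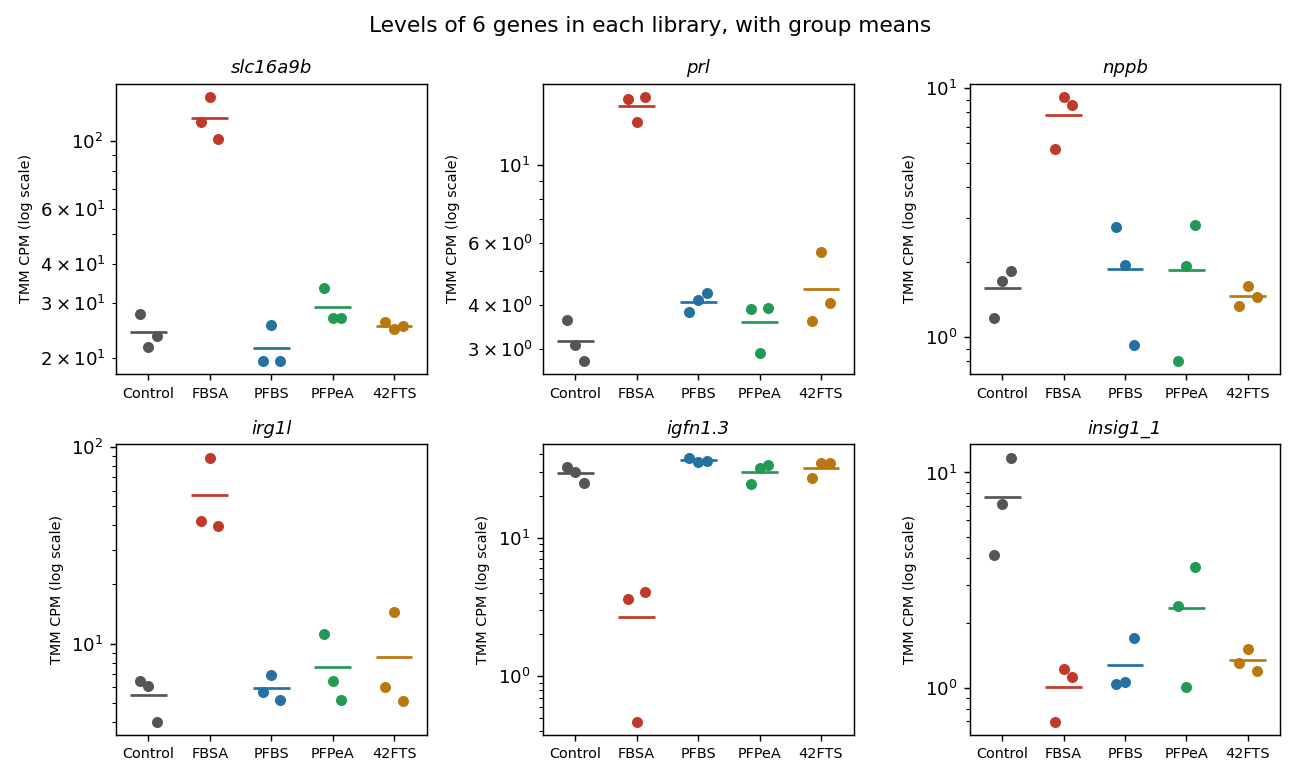
Levels of slc16a9b, prl, nppb, irg1l, igfn1.3 and insig1_1 in the 15 libraries, as TMM-scaled CPM on a log axis, with dots for libraries and bars for group means. The mean of slc16a9b is 118 in FBSA and 21.5 to 29.0 in the other groups, and the mean of insig1_1 is 7.67 in the control and 1.01 to 2.35 in the exposed groups.

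Direct tests between compounds at the same exposure concentration and time separated FBSA from each of the others. Levels of the compounds in the embryos were not analysed, so differences in uptake cannot be told apart from differences in effect. Between the sulfonamide FBSA and the sulfonic acid PFBS 2423 genes differed, 1234 higher and 1189 lower in FBSA. Higher in FBSA were slc16a9a (3.91, 95% CI 2.90 to 4.93), irg1l (3.26, 2.21 to 4.31), tph1b_1 (2.81, 1.70 to 3.93), endouc_1 (2.64, 0.97 to 4.31) and slc16a9b (2.46, 2.16 to 2.76). Lower were igfn1.3 (-3.75, -4.76 to -2.74), tmx2a (-2.95, -4.12 to -1.79), myhb (-2.25, -3.15 to -1.34), gc (-2.09, -3.42 to -0.76) and aglb (-2.01, -2.70 to -1.32). The calls of endouc_1 (any of the 6 libraries, 2.03 to 2.91) and gc (any but FBSA 1, -2.33 to -1.64) were lost when 1 library was left out, with folds of similar size. The count was 1159 without FBSA 2, 1508 without PFBS 2, 1443 without PFBS a and 934 in a fit of only the 2 groups, which lost the calls of igfn1.3 (-3.75) and gc (-2.09). Without the low-count filter those of endouc_1 (2.64) and gc (-2.09) were lost. The suffixed entries tph1b_1 and endouc_1 are uncertain, and tph1b_1 deviated from its group means against its stem tph1b (r = -0.357).

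Between FBSA and PFPeA 1971 genes differed, 974 higher and 997 lower in FBSA. Higher were rnaseh2b (5.53, 95% CI 2.58 to 8.49), irg1l (2.89, 1.86 to 3.92), slc16a9a (2.79, 1.85 to 3.73), epm2a (2.56, 1.85 to 3.26) and agxtb (2.48, 1.41 to 3.54), and lower were tmx2a (-4.15, -5.32 to -2.98), igfn1.3 (-3.47, -4.48 to -2.46), mrps16_1 (-2.94, -3.97 to -1.91), the creatine kinase gene ckmt2a (-2.47, -3.56 to -1.38) and clta (-2.12, -2.95 to -1.28). The call of rnaseh2b was lost without FBSA 2, FBSA 3 or any PFPeA library (4.96 to 5.95), that of agxtb without FBSA 2 (1.79) and that of ckmt2a without PFPeA 3 (-1.82). The count was 787 without FBSA 2, 934 and 908 without PFPeA 2 and PFPeA 3, and 438 in a fit of only the 2 groups, which lost the calls of irg1l (2.89), igfn1.3 (-3.47) and mrps16_1 (-2.94). Without the low-count filter that of rnaseh2b (5.53) was lost. PFPeA itself stood above the control in tmx2a (3.52) and mrps16_1 (2.80), neither past the test. The differences in these genes thus lie mostly in PFPeA.

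Between FBSA and 42FTS 2339 genes differed, 1358 higher and 981 lower in FBSA. Higher were slc16a9a (2.94, 95% CI 1.99 to 3.89), irg1l (2.74, 1.72 to 3.76), lrrc58a (2.53, 1.67 to 3.38), the muscle gene tcap (2.47, 1.02 to 3.92) and nppb (2.42, 1.53 to 3.31), and lower were igfn1.3 (-3.57, -4.58 to -2.56), the entry gb:cr929477_1 (-2.39, -3.65 to -1.12), myhb (-1.82, -2.73 to -0.91), aglb (-1.73, -2.41 to -1.04) and lgals3bpb (-1.70, -2.26 to -1.14). The call of tcap was lost without FBSA 2, FBSA 3, 42FTS 1 or 42FTS 3 (2.08 to 2.48), that of gb:cr929477_1 without FBSA 1, FBSA 2, 42FTS 1 or 42FTS 2 (-2.34 to -2.01), and that of myhb without 42FTS 3 (-1.55). The count was 999 without FBSA 2, 1390, 1441 and 1253 without 42FTS 1, 2 and 3, 1339 without Control 3 and 42FTS 2 together, and 788 in a fit of only the 2 groups. That fit lost the calls of irg1l (2.75), tcap (2.48), igfn1.3 (-3.57), gb:cr929477_1 (-2.39), myhb (-1.82) and aglb (-1.73), and without the low-count filter that of tcap (2.47) was lost.

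Of the 24 genes named for FBSA against the control, 17 passed the direct test against PFBS, 15 against PFPeA and 15 against 42FTS, and 12, 8 and 9 in fits of only the 2 groups. By edgeR those that did not pass in any of the 3 were irf3, maff, insig1_1, nat9_1, tomm22, znf839_1 and magoh. Of these DESeq2 called maff against PFBS (1.54) and insig1_1 (-1.22) and tomm22 (-1.81) against PFPeA, and by edgeR maff passed against PFBS (1.92) and 42FTS (1.72) without FBSA 3 and insig1_1 against PFPeA (-1.56) without PFPeA 2. For insig1_1 the difference between FBSA and PFBS was -0.33 (95% CI -1.29 to 0.63), and for magoh it was 0.03 (-1.26 to 1.32), intervals that still allow more than a 2-fold difference. In all, 1129 genes were called in FBSA against each of the 4 other groups in the same direction, 640 higher and 489 lower. The 4 comparisons share the FBSA libraries, so this count does not come from independent tests. The cell cycle list was higher in FBSA than in PFBS, PFPeA and 42FTS (adjusted p = 4.6e-13, 2.8e-11 and 2e-13, with 18, 12 and 19 of 35 members higher, and 25, 24 and 22 adjusted over the list alone), and the neuron list lower (adjusted p = 1.2e-11, 3.9e-10 and 7.3e-09, with 18, 16 and 16 of 39 members lower, and 23, 22 and 19 adjusted over the list alone). With an estimated correlation the adjusted p was 0.091, 0.12 and 0.11 for the cell cycle and 0.18, 0.24 and 0.26 for neurons. Cell cycle genes past the test were 11 against PFBS without FBSA 2, 7 and 6 against PFPeA without FBSA 2 and PFPeA 3, and 10, 11 and 12 against 42FTS without FBSA 2, 42FTS 2 and 42FTS 3, where 7 neuronal genes passed without 42FTS 3. Heart (0.00036, 0.0021 and 0.0022), ionocytes (0.0014, 0.0046 and 0.01), the hatching gland (6.5e-06, 0.00017 and 5.4e-05) and vessels (0.0025, 0.0079 and 7e-05) were also higher by adjusted p. With an estimated correlation these 4 had an adjusted p of 0.035 against PFBS and 0.059 against PFPeA. Against 42FTS that p was 0.023 for vessels, 0.052 for heart and the hatching gland and 0.068 for ionocytes.

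Genes of oxidative phosphorylation were lower in FBSA than in each of the other compounds. Of 58 members 8 fell against PFBS and PFPeA and 2 against 42FTS, and 16, 15 and 0 adjusted over the list alone (adjusted p = 4.3e-09, 1.2e-08 and 0.0026, and 0.27, 0.28 and 0.50 with an estimated correlation). The last of these was not called without 42FTS 3 (0.0542). Against PFBS, 2 members passed without FBSA 2, PFBS 2 or PFBS a and 13 without PFBS b, and against PFPeA, 0 passed by edgeR without FBSA 2 or PFPeA 3 and 1 without PFPeA 2. Against 42FTS, 4 passed without FBSA 1, 1 without 42FTS 1 or 42FTS 2, and 0 by edgeR without FBSA 2 or 42FTS 3. Skeletal muscle genes were lower in FBSA than in PFBS, with 14 of 62 members lower and 5 higher, and 20 and 7 adjusted over the list alone (adjusted p = 0.0014, and 0.31 with an estimated correlation). In that comparison 6 were lower without FBSA 2 and 8 without PFBS 2, and 3 were higher without PFBS 2 and 2 without PFBS a or PFBS b. Against PFPeA, 13 were lower and 4 higher, and 18 and 6 adjusted over the list alone (adjusted p = 0.0089, 0.49 with an estimated correlation, 0.0557 without FBSA 2 and 0.120 without PFPeA 3), with 5 lower and 2 higher without FBSA 2 or PFPeA 3 and 7 lower without PFPeA 2. Sterol biosynthesis was higher in FBSA than in PFPeA, with cyp51 (0.85) and hsd17b7 (0.58) higher, and 4 of 25 adjusted over the list alone (adjusted p = 0.016, 0.69 with an estimated correlation, 0.481 without FBSA 2 and 0.083 without PFPeA 1). Of the sterol genes 4 passed higher without FBSA 1, 1 without PFPeA 3 and 0 by edgeR without FBSA 2, PFPeA 1 or PFPeA 2. Lens crystallins were higher in FBSA than in 42FTS, with 8 of 40 higher and 1 lower, and 11 and 1 adjusted over the list alone (adjusted p = 0.0022, 0.47 with an estimated correlation and 0.0606 without FBSA 1). Of the lens genes 1 passed higher without FBSA 1, 42FTS 1 or 42FTS 2 and 2 without FBSA 3, and 2 passed lower without FBSA 1 and 0 by edgeR without FBSA 2.

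Between the acids, by edgeR 0 genes differed between PFBS and 42FTS, between PFBS and PFPeA, and between PFPeA and 42FTS, with 1047, 1154 and 1629 genes at an unadjusted p under 0.05 and 12, 15 and 26 genes by DESeq2. The lowest p belonged to ap1g2_1 (0.42, 95% CI 0.26 to 0.58) for PFBS against 42FTS, to mrps16_1 (-2.93, -3.97 to -1.90) for PFBS against PFPeA and to bmp2k (-0.75, -1.03 to -0.47) for PFPeA against 42FTS, with adjusted p = 0.906, 0.335 and 0.322. Also named without passing by edgeR were mtor (-0.78) and bmpr2b (-1.11), pex5_2 (-2.19) and suz12b (1.41), and rorb (-1.52) and gpm6aa (0.32), in the same order of comparisons, and DESeq2 called all 9 of these genes. By edgeR mrps16_1 (-3.39) and suz12b (1.87) passed for PFBS against PFPeA without PFPeA 3. The median confidence interval of a difference was 0.44 to either side in each of the 3 comparisons, so smaller differences lay within the error of a typical gene. For the 24 genes named for FBSA the intervals reached from -2.01 to 2.51 between PFBS and 42FTS, from -2.80 to 2.70 between PFBS and PFPeA and from -1.91 to 2.90 between PFPeA and 42FTS. Over all genes tested, the median absolute log2 change against the control was 0.23 for FBSA, 0.12 for PFBS, 0.13 for PFPeA and 0.13 for 42FTS.

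Fold changes of the 4 compounds correlated with each other across genes, with a mean r of 0.446 over the 6 pairs of compounds (0.384 to 0.508). The 4 comparisons share the 3 control libraries, and simulated groups without any change, set against the same controls in 20 simulations, gave a mean r of 0.434. The mean covariance was 0.0676 against a simulated 0.0523. With the controls simulated as well, r was 0.502 and the covariance 0.0685. The simulated levels were averages over all libraries but those of FBSA, the controls included. That placed the simulated groups nearer to the real controls, so 0.434 and 0.0523 are likely too low for unchanged groups. The mean r also includes the pairs with FBSA, which had the lowest r (0.384 to 0.422). Both means with simulated controls lay above the measured means, so shared controls alone could give means of the measured size. Single pairs did not all follow. The covariance of FBSA with PFPeA (0.0742) and with 42FTS (0.0697) lay above that with simulated controls (0.0684 for both). So did the r of PFBS with 42FTS (0.508 against 0.503). The other values of the pairs lay under those with simulated controls.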

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

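The tests of the neuronal, progenitor and cell cycle pattern below were chosen after the result was seen, and the counts over splits of the libraries were planned before it.

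The change that FBSA made against the control differed from that of each other compound by a direct test at the same exposure concentration and time. The number of genes past that test was 2423 against PFBS, 1971 against PFPeA and 2339 against 42FTS. Libraries were regrouped into the 10 possible splits of 3 against 3 for each comparison. For FBSA against the control the real split gave 2274 genes and the highest other 1, for FBSA against PFBS 2423 and 0, for FBSA against PFPeA 1971 and 1, and for FBSA against 42FTS 2339 and 1, and 1 split of the 10 (the real split itself) gave as many in each. The real split gave 0 genes for PFBS, PFPeA and 42FTS against the control (highest other 1, 2 and 2) and for PFBS against 42FTS, PFBS against PFPeA and PFPeA against 42FTS (highest other 0, 1 and 1), so all 10 splits gave as many in each. The 10 splits are too few for a share under 0.05.

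Neuronal genes were lower and genes of neural progenitors and the cell cycle higher in FBSA, most of all in FBSA 2. With an estimated correlation these 3 lists were not called. Control 3 scored -0.117 for neurons, under the -0.103 of FBSA 1. FBSA 2 also had 29284 genes detected (28203 to 29182 in the other 14 libraries) and 0.789% of counts in mitochondrial genes (0.480% to 0.761%). The tables argue against FBSA 2 alone as the source: without it 27 members of the 3 lists were still called in the list's direction, with medians of -0.18 for neurons, 0.16 for progenitors and 0.20 for the cell cycle, against -0.27, 0.45 and 0.28 with it. An even loss of neural tissue would not by itself raise the progenitor list. All 3 FBSA libraries scored higher on that list (0.172 to 0.486) than the other 12 (at most 0.0367), with a median of 0.447. The list is part of the pattern, so its rise was known beforehand and is not a separate test. Its adjusted p was 0.077 with an estimated correlation. A lower share of neurons alone stays open. A general delay of development remains possible as an explanation. Of 12 tissue lists 1 was lower, the neuron list of the pattern itself, and 3 were higher. The hatching gland list, also called higher, was not among the 12. No library of another age was available to compare. Apart from these explanations, no biological one beyond the exposure itself was tested.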

How the results depend on the processing

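Counts of changed genes depended on single libraries and on the model more than on scaling. For FBSA against the control RLE scaling gave 2276 genes, DESeq2 3102, no low-count filter 1954 and summed copies 2650. At least 2-fold changes were 302, a fit of only the 2 groups gave 855 (807 shared with the 2274), omission of Control 3 and 42FTS 2 gave 1228, and leaving out 1 library gave 1020 to 2108 (976 shared without FBSA 2). The same 4 values were 293, 934, 2123 and 1159 to 2242 against PFBS, 256, 438, 1622 and 787 to 1877 against PFPeA, and 286, 788, 1339 and 999 to 2165 against 42FTS. In the comparisons with 0 genes, DESeq2 gave 6 for PFBS, 15 for PFPeA and 14 for 42FTS against the control, 12 for PFBS against 42FTS, 15 for PFBS against PFPeA and 26 for PFPeA against 42FTS. Fits of only the 2 groups gave 1 (PFBS), 4 (42FTS), 1 (PFBS against 42FTS) and 2 (PFPeA against 42FTS), no low-count filter gave 1 for PFPeA, and omission of Control 3 and 42FTS 2 gave 1 for 42FTS. Leaving out 1 library gave 0 to 1 for PFBS, 0 to 2 for PFPeA, 0 to 2 for 42FTS, 0 to 1 for PFBS against 42FTS, 0 to 3 for PFBS against PFPeA and 0 to 1 for PFPeA against 42FTS.

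Lists called with an estimated correlation were 4 for FBSA, 0 for PFBS, 1 for PFPeA and 0 for 42FTS against the control, and 4, 0 and 1 for FBSA against PFBS, PFPeA and 42FTS. The fry test called 0 for PFBS, PFPeA and 42FTS, and omission of Control 3 and 42FTS 2 left 2 for PFBS and 0 for 42FTS. Leaving out 1 library gave 14 to 19 lists for FBSA, 3 to 7 for PFBS, 4 to 7 for PFPeA, 0 to 4 for 42FTS, and 16 to 21, 15 to 19 and 15 to 21 for FBSA against PFBS, PFPeA and 42FTS. The shared direction of fold changes (r = 0.446) was 0.528 to 0.563 without 1 control. Unchanged groups simulated against the same 2 controls gave 0.546 to 0.580 (mean 0.561), and 0.597 to 0.608 (mean 0.603) with the controls simulated too, against 0.434 and 0.502 with 3 controls. The log2 difference in magoh changed sign against PFBS without PFBS 2 (-0.042) or PFBS b (-0.045), with a range of -0.045 to 0.200 over left-out libraries (0.032 with all), and against 42FTS without 42FTS 1 (0.093), with a range of -0.59 to 0.093 (-0.389 with all). Of the 24 genes named for FBSA, 13 passed under every alternative with a test that was fixed before the data were examined. Among these alternatives igfn1.3, ampd1 and myhb lost the call only in the fit of the 2 groups. The alternatives added after the data were seen were not examined for single named genes.

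Library numbers were tested as a block, since nothing in the labels says whether they pair the libraries. The mean correlation of deviations from the group mean was 0.0473 for libraries with the same number and -0.0235 for others. Deviations in a group sum to 0, so the second mean follows closely from the first. A correlation over 0.1 was found in 6 of 18 pairs with the same number and in 2 of the 36 others. With the block FBSA against the control gave 2035 genes (2009 without the block or PFBS), against PFPeA 1740 (1710) and against 42FTS 2072 (2046), and 0 in the others. With the block the calls of tomm22, magoh, cox6b1 (-0.91) and hoxb6b (-2.25) against the control, rnaseh2b (5.59) against PFPeA, and tcap (2.44) and gb:cr929477_1 (-2.27) against 42FTS were lost, and cyp2ad3 (0.37) passed. The block fit called 18, 6 and 2 lists for FBSA, PFPeA and 42FTS against the control and 19 each for FBSA against PFPeA and 42FTS. No paired analysis was possible for PFBS, because its libraries do not all carry numbers.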

Other observations

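The genes that told FBSA from another compound were followed in comparisons that share no library with that test. The 2423 genes of FBSA against PFBS had a median signed log2 of 0.45 in their own comparison. It was 0.02 in PFPeA against the control (57.0% in the same direction) and 0.01 in 42FTS (52.4%). Their mean signed score over the control mean was 0.0869 in PFPeA 1, 0.0020 in PFPeA 2 and -0.0110 in PFPeA 3. The mean score of PFPeA thus rested on PFPeA 1. The 2339 genes of FBSA against 42FTS had medians of -0.00 in PFBS (48.4%) and 0.04 in PFPeA (63.7%), and the 1971 of FBSA against PFPeA -0.01 in PFBS (45.6%) and 0.01 in 42FTS (55.0%). Compared without the controls, the sterol list was called between PFPeA and PFBS or 42FTS, only with the preset correlation. It was higher in PFBS than in PFPeA (median 0.33, adjusted p = 9.6e-09, and 0.70 with an estimated correlation). It was lower in PFPeA than in 42FTS (median -0.35, adjusted p = 1.9e-07, and 0.50 with an estimated correlation). Between PFBS and 42FTS the list was not called (median -0.01, adjusted p = 0.99). In each of these comparisons 0 of 25 genes passed the test over all genes.

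For the 2 patterns that follow, all tests were chosen after the result was seen, except that of numbered copies, which was fixed before it.

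Sterol biosynthesis was called lower in all 4 compounds against the same 3 controls with the preset correlation, but in none with an estimated one (adjusted p = 0.52 for FBSA, 0.87 for PFBS, 0.13 for PFPeA and 0.90 for 42FTS), and FBSA 2 scored 0.0559, within the range of the controls (-0.113 to 0.171). High control libraries stay open as an explanation for PFPeA: its list score (mean -0.526) lay under that of PFBS and 42FTS (mean -0.239), but with the most extreme of the 4 compounds taken in each of 15400 regroupings of the exposed libraries the exact permutation p was 0.18, and 0.036 over 280 regroupings without FBSA. Control 3 alone is argued against for PFPeA, since the median was -0.39 without it (-0.54 with it). For PFBS and 42FTS Control 3 alone stays open as an explanation: without it 0 of the 2 comparisons still called the list, with medians of -0.07 in both against -0.18 and -0.20. No biological explanation beyond the exposures was tested.

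Several large decreases in FBSA had levels that scattered between the controls. Of the 12 named decreases 6 had controls that differed over 2-fold, against 3 of the 12 named increases. Of those 6, 5 also had a median log2 under -1 over the other 3 compounds: insig1_1, nat9_1, tomm22, znf839_1 and magoh. All these comparisons share the 3 controls, and the genes were picked for lying below them in FBSA. High control levels alone could therefore give such decreases. By edgeR with all libraries, these 5 genes did not pass any direct test of FBSA against another compound. Reads split between numbered copies of a gene stay open, with a median correlation of -0.199 between a copy and its stem over 79 called copies, but only 2 of the 6 genes are among these, nat9_1 (0.33) and znf839_1 (-0.30), so that median says little of the 6. A variant carried by some embryos of a pool stays open too, with a median pairwise correlation of 0.225 between the scattered genes, since no sequence was available to compare.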
